A study of Homo sapiens with 11 samples.

How the data were processed

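RNA was analysed from U251 cells carrying inducible mutant APP. Per the labels' protocols, cells were electroporated with 2.5 µL of 20 µM siRNA or 10 µg of plasmid, doxycycline was added at 1 µg/mL after 24 h to induce APP, and cells were harvested at 72 h. Libraries were made from 1.5 µg of total RNA, and the titles describe the replicates of each group as biological. Groups and replicate numbers were taken from the sample titles: siNC, si-YAP1 and vector with 3 libraries each, and YAP1 with replicates 1 and 3.

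The deposited values are on a log2 scale: 1 table of regularised log2 (rlog) values that the authors made with DESeq2, per the submitters' processing notes and the table's name. Those notes also name Trimmomatic 0.33, TopHat, HTSeq 0.6.1p1 and the genome build GRCh38.p7. The rlog transformation adjusts for library size and draws the values of weakly expressed genes towards their mean over libraries, so that differences between groups are understated for such genes. Values ran from -3.48 to 19.34. Read counts were not used here, so the depth per library is unknown, no interval for counting error is given, and no count model was fitted. Whether counting used the strand is not given in the sources used here, so reads of genes that overlap on opposite strands may be mixed, and reads of near-identical genes may be shared.

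Of 25159 gene identifiers, 24060 matched GENCODE release 29 on GRCh38, from which symbols, positions, and the GC content and length of each gene's longest transcript were taken. The other 1099 kept their identifiers. No gene of the mitochondrial chromosome was in the table. Genes with a mean over all libraries of at least 3 were tested (15681), and 97.3% of these had a release 29 transcript.

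All 11 libraries were fitted in 1 linear model of 4 group means with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, 7 residual and 10.9 prior degrees of freedom). The 3 comparisons were si-YAP1 minus siNC, YAP1 minus vector and vector minus siNC, with the difference of the first 2 as a further contrast. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and genes with an adjusted p under 0.05 were called. Changes are given on the rlog scale with limma's standard error, and group levels as mean and SD. YAP1 was also tested by exact permutation of the libraries (numpy 2.4.6). Figures were drawn with matplotlib 3.10.9.

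The gene lists (21), the rule for named genes and the first group of alternative settings below were fixed before the data were examined. The mitochondrially encoded list had no member in the table and the microglia and leukocyte list had 1 tested member, which left 19 with at least 5. Each was compared with all other tested genes by camera at a preset correlation of 0.01, adjusted over the 19 lists and 3 comparisons, and again with the correlation estimated per list. The rotation test fry asked separately whether a list's genes moved, on balance, one way, without reference to other genes.

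The rule for named genes took YAP1, the 10 largest rises and 10 largest falls among called genes with an approved symbol and no overlap between groups, up to 3 members of each list by smallest adjusted p, and the 5 genes called in both comparisons in opposite directions with the largest smaller change, and none were called in both in the same direction. For vector against siNC the rule took 5 rises, 5 falls and members of called lists. APP, CTGF, CYR61, ANKRD1, RPS18 and ENSG00000184779 lie outside the rule, wholly or in part, and were named after their values were seen.

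That first group was no filter or a mean of at least 5, no trend, robust eBayes, quantile normalisation, centring on library medians, fitting only the groups compared, the replicate number as a block, a minimum change of 0.5, an estimated correlation, fry, and leaving out each of the 11 libraries. Alternatives chosen after seeing the data were 3. The first subtracted, per library, a natural spline with 5 degrees of freedom of the deviations from gene means on transcript GC content and on log2 length. The second used each library's GC slope as a covariate. The third left out both si-YAP1 replicate 2 and vector replicate 3, the libraries whose values fell most with GC content. The model was tested on simulated data for 15681 genes with 100 genes changed by 0.3 and 100 by 0.6. It recovered 72, 68 and 76 of the former in the knockdown, overexpression and control comparisons, and 100 of the latter in each, with 9, 14 and 16 false calls. Values were simulated independently for each gene and library. These counts therefore do not describe errors from differences that many genes of a library share.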

Results

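Gene expression was measured by RNA sequencing in U251, a human glioblastoma cell line, stably carrying a mutant form of APP, the amyloid precursor protein, whose expression is induced with doxycycline. YAP1, a transcriptional coactivator restrained by the Hippo pathway, was either knocked down with siRNA or overexpressed from a plasmid, and the comparisons ask which genes respond to its level. The 11 libraries comprised 3 with control siRNA (siNC), 3 with siRNA against YAP1 (si-YAP1), 3 with the vector alone and 2 with the YAP1 plasmid. A further YAP1 library was removed by the submitters as an outlier, per the series design, and was not analysed here. Values were regularised log2 (rlog) expression values for 25159 genes, of which 15681 with a mean of at least 3 were tested. Read counts were not analysed here, so the depth behind each value is unknown, and the regularisation understates the changes of weakly expressed genes. APP was the highest of all genes in each of the 11 libraries, with rlog values between 19.01 and 19.34.

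The libraries differed in sequence composition as well as in group. The first principal component held 46.4% of the variance and had si-YAP1 replicate 2 and vector replicate 3 at one end, with the siNC and YAP1 libraries at the other. In these 2 libraries, deviations from each gene's mean fell with transcript GC content across genes (Spearman's rho -0.567 and -0.584). Vector replicate 2 had the next lowest rho, -0.392. In vector replicate 1 and si-YAP1 replicates 1 and 3 it was 0.102, -0.037 and 0.195. In the siNC and YAP1 libraries rho lay between 0.296 and 0.414. Genes are not independent replicates, so these values describe the libraries.

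**Figure D1:**
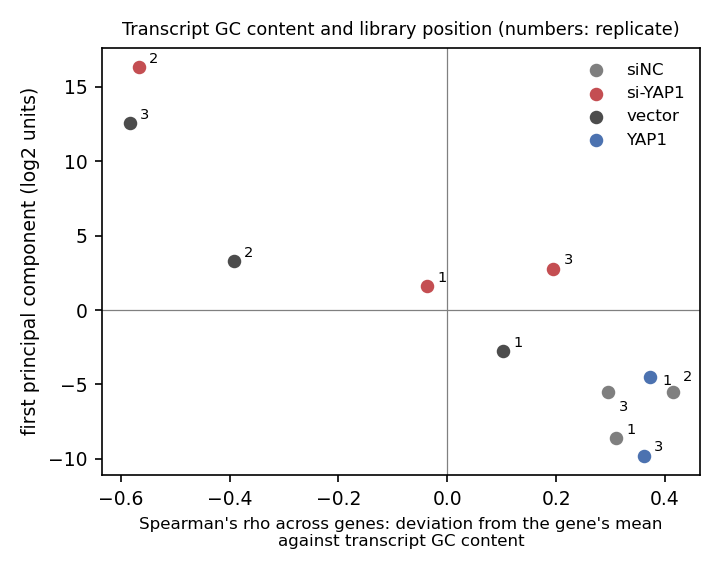
Each point is a library; the x axis is Spearman's rho across genes between its deviations from each gene's mean (log2) and transcript GC content, and the y axis its score on the first principal component (log2 units). Replicate 2 of si-YAP1 and replicate 3 of vector lie apart from the rest, with rho of -0.567 and -0.584, and siNC and YAP1 libraries lie together at the other end. Replicate 2 of vector has the next lowest rho, -0.392.

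YAP1 itself (ENSG00000137693, GRCh38 chromosome 11, 102110461 to 102233423) was lower in every si-YAP1 library than in any siNC library, and higher in both YAP1 libraries than in any vector library. Its level was 11.88 ± 0.07 in si-YAP1 and 12.07 ± 0.05 in siNC (SD, n = 3 each), a difference of -0.19 ± 0.06 (SE), or -12.4% on the linear scale. This difference did not pass the limma test (adjusted p = 0.0700), and the exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it allows. Under the YAP1 plasmid the level was 12.49 ± 0.02 (SD, n = 2) against 12.13 ± 0.07 in vector (SD, n = 3), a rise of 0.36 ± 0.07 (SE), or 28.5% (limma adjusted p = 0.0106). The exact permutation test of the 10 splits of these 5 libraries gave p = 0.1. Transcripts from the plasmid and from the endogenous gene are not separated in these values. The knockdown difference passed the limma test with values centred on library medians (-0.28, adjusted p = 0.00929), quantile normalised (-0.28, adjusted p = 0.0122) or corrected for GC content and length (-0.30, adjusted p = 0.00313), and without si-YAP1 replicate 3 (-0.23, adjusted p = 0.0490) or vector replicate 3 (-0.19, adjusted p = 0.0498), within a range of 0.00313 to 0.214 over its alternatives. The overexpression call was lost when YAP1 replicate 1 (0.38, adjusted p = 0.0788) or YAP1 replicate 3 (0.35, adjusted p = 0.329) was left out.

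**Figure D2:**
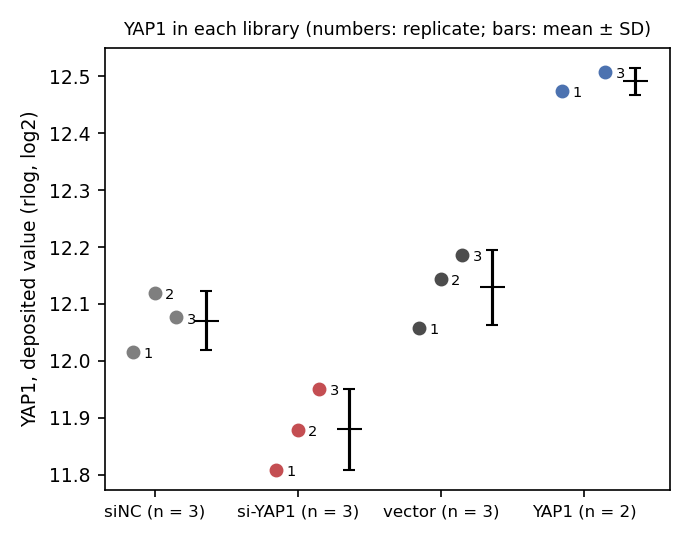
Points are the deposited rlog (log2) values of YAP1 in each library by group, numbered by replicate, with the group mean and SD beside them; the y axis does not start at 0. The 3 si-YAP1 libraries average 11.88 against 12.07 in siNC, and the 2 YAP1 libraries average 12.49 against 12.13 in vector.

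The knockdown comparison asks which genes respond to less YAP1. KRT81, a hair keratin gene (chromosome 12, 52285913 to 52291534) had the largest fall, from 10.62 ± 0.06 in siNC to 9.97 ± 0.09 in si-YAP1 (SD, n = 3 each), a change of -0.65 ± 0.07 (SE; limma adjusted p = 0.000909). The largest rise was in NPY1R, a neuropeptide Y receptor (chromosome 4, 163323961 to 163344832), from 13.54 ± 0.32 to 14.31 ± 0.17, by 0.76 ± 0.13. In vector, KRT81 was at 10.22, between its siNC and si-YAP1 levels, NPY1R was at 14.38 and YAP1 at 12.13. Of the genes tested, 747 passed the threshold, 716 of them higher and 31 lower in si-YAP1, and 3242 had an unadjusted p under 0.05. Among the other large rises were SAMD9, an interferon-inducible antiviral factor (0.72 ± 0.12), and the kinetochore genes CENPF (0.70 ± 0.14) and KNL1 (0.61 ± 0.11). SYNE2, a nuclear envelope protein, rose by 0.70 ± 0.13, the spindle pole gene ASPM by 0.68 ± 0.12 and the nucleoporin RANBP2 by 0.67 ± 0.11. PHIP rose by 0.65 ± 0.11, and the chromatin remodellers CHD9 and ATRX by 0.62 ± 0.10 each. Their adjusted p-values lay between 0.00500 and 0.00940. In vector, each of these other rises lay between its siNC and si-YAP1 levels, as for CENPF (10.73, against 10.33 and 11.03). Part of each rise was thus also present between the controls. Reads of RANBP2 and KRT81 may be shared with near-identical family members, so their values are less certain than the rest.

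Other falls after knockdown were smaller than that of KRT81. HKDC1, a hexokinase, fell by 0.44 ± 0.06 (SE), the carboxypeptidase gene CPA4 by 0.41 ± 0.08 and BEX2 by 0.39 ± 0.08. The adhesion genes PCDH1 and CDH13 fell by 0.38 ± 0.09 and 0.38 ± 0.06. ALDH1A3, an enzyme of retinoic acid synthesis, fell by 0.38 ± 0.08 and the netrin receptor UNC5B by 0.34 ± 0.07. TRIB3, a pseudokinase induced by ATF4, fell by 0.33 ± 0.07 and GDF15, a stress-induced cytokine, by 0.31 ± 0.07. Adjusted p-values of these 9 genes lay between 0.00475 and 0.0223. In vector, where YAP1 was at 12.13, PCDH1 (7.32), ALDH1A3 (9.88), UNC5B (7.14), TRIB3 (10.95) and GDF15 (12.20) lay below si-YAP1. Their si-YAP1 levels were 7.44, 9.96, 7.24, 11.10 and 12.36. Vector levels of HKDC1, CPA4, BEX2 and CDH13 lay between those of si-YAP1 and siNC. For the genes lower still in vector, a high siNC level cannot be told apart from a response to less YAP1. The genes that rose had long transcripts of low GC content, with a median of 39.1% GC and 6222 bases against 48.0% and 3314 bases over all genes, and those that fell had a median of 54.1% GC. The split of calls moved with scaling, to 246 higher and 189 lower with median centring, 239 and 82 with quantile normalisation, and 266 and 152 with the GC and length correction, which was chosen after seeing the data. Leaving out siNC replicate 1, 2 or 3 left 82, 178 and 360 calls, and leaving out si-YAP1 replicate 2 left 238; of the 40 named genes called, 25, 19, 11 and 14 lost their call without these libraries in turn.

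Cell cycle genes as a group were higher after knockdown. All 29 tested members of the DNA replication and S phase list lay above 0, with a median change of 0.20, and 6 rose, or 28 adjusted over the list alone. They included CLSPN, a replication checkpoint mediator (0.36 ± 0.07 SE, limma adjusted p = 0.0112), the ribonucleotide reductase subunit RRM2 (0.33 ± 0.07, adjusted p = 0.0185) and ORC1, of the origin recognition complex (0.28 ± 0.06, adjusted p = 0.0185). Of the 30 members of the mitosis and G2/M list, 8 rose and 0 fell, or 21 and 0 adjusted over the list alone, with a median change of 0.19. TOP2A, a DNA topoisomerase (chromosome 17, 40388516 to 40417950), rose from 12.98 ± 0.07 to 13.55 ± 0.16 (SD, n = 3 each) and the mitotic kinesin KIF11 rose by 0.41 ± 0.08. Both lists were higher than other genes by camera (adjusted p = 3.59e-11 and 1.19e-08; adjusted p = 0.724 for each with an estimated correlation). Of 16 glial and neural stem cell markers 3 rose, or 7 adjusted over the list alone, and the list was higher by camera (adjusted p = 0.00262; adjusted p = 0.724 with an estimated correlation). They were GFAP, an astrocyte intermediate filament (0.53 ± 0.10, adjusted p = 0.00768), ID3 (0.30 ± 0.07, adjusted p = 0.0218) and the glutamate transporter SLC1A3 (0.27 ± 0.06, adjusted p = 0.0236). In vector, SLC1A3 was at 11.69, against 11.60 in si-YAP1 and 11.33 in siNC. GFAP in vector (16.17) lay between si-YAP1 (16.30) and siNC (15.77), and ID3 in vector (12.47) near siNC (12.49). Calls of ID3, SLC1A3 and ORC1 ended with quantile normalisation and median centring, and that of RRM2 with median centring. The si-YAP1 library with the lowest rho with GC content, replicate 2, had the highest list medians of deviations from gene means, 0.24 for mitosis (0.07 and 0.01 in replicates 1 and 3), 0.17 for DNA replication (0.09 and 0.0029) and 0.16 for glial markers (0.02 and -0.02). Without it and vector replicate 3 the median changes were 0.13, 0.17 and 0.09 (camera adjusted p = 1.46e-07, 1.57e-10 and 0.0370).

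Lists of stress, translation and YAP1 target genes were lower than other genes by camera after knockdown, each with an adjusted p of at least 0.724 once the correlation was estimated. In the ATF4 and unfolded protein response list (camera adjusted p = 5.44e-11, median -0.07), 2 of 30 members fell and 1 rose, or 4 and 1 adjusted over the list alone, and 7 fell and 0 rose with the GC and length correction. CHAC1, a glutathione-degrading enzyme, fell by 0.31 ± 0.06 (limma adjusted p = 0.0112) beside TRIB3, and SLC7A11, a cystine transporter, rose by 0.35 ± 0.09 (adjusted p = 0.0413). The 30 cytosolic ribosomal proteins (camera adjusted p = 6.73e-09, median -0.05) and 21 NF-kB and cytokine genes (adjusted p = 0.000237, median -0.04) held 0 members past the limma test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1 ribosomal protein was lower, as were 2 NF-kB list members, with 1 higher. Without si-YAP1 replicate 3 the ribosomal call was lost (adjusted p = 0.0838) and its median was 0.04. The lowest adjusted p among them belonged to RPL4 (-0.12 ± 0.06, adjusted p = 0.242) and IL11 (-0.24 ± 0.08, adjusted p = 0.102). The YAP/TAZ target signature of 22 genes was called lower (camera adjusted p = 0.00825), although its median change of 0.0072 and mean of 0.0055 lay just above 0 and below the median of all genes, 0.06. With median centring its median was -0.09 and the call was lost (adjusted p = 0.0966). RBMS3 rose by 0.23 ± 0.06 (adjusted p = 0.0373), and adjusted over the list alone CCDC80 (-0.23 ± 0.07) and the receptor kinase AXL (-0.20 ± 0.06) fell as well. In vector, RBMS3 was at 9.94, against 9.92 in si-YAP1 and 9.69 in siNC, and AXL at 13.90, against 13.90 and 14.10. CCDC80 in vector (11.59) lay between si-YAP1 (11.42) and siNC (11.66). With the GC and length correction the median was -0.06, the list was called lower (adjusted p = 0.00319; adjusted p = 0.228 with an estimated correlation) and the members past the limma test over all genes were 3 lower and 0 higher. The YAP1 targets CTGF (-0.08 ± 0.07), CYR61 (-0.13 ± 0.07) and ANKRD1 (0.10 ± 0.07), named here after their values were seen, did not pass the test. Of 29 hypoxia and glycolysis genes 0 passed the limma test, and at an unadjusted p under 0.05, 3 were higher and 1 lower. As a list they were called lower by camera (adjusted p = 0.0485), with a median of 0.0011 and a mean of 0.02. This call was lost with median centring (adjusted p = 0.0635) and without si-YAP1 replicate 1 (0.0962) or 3 (0.147), siNC replicate 2 (0.0772) or 3 (0.128), or vector replicate 1 (0.0511) or 3 (0.0546).

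Among lists not called in the knockdown comparison, single members changed. Of 33 genes of APP processing and Alzheimer risk (camera adjusted p = 0.924, median 0.08), the alpha-secretase gene ADAM10 rose by 0.24 ± 0.06 (SE; limma adjusted p = 0.0319). APP, named here after its values were seen, stood at 19.22 ± 0.08 against 19.10 ± 0.08 (SD, n = 3 each; adjusted p = 0.317). The Hippo list (adjusted p = 0.157, median 0.11) had 1 call of 26, MOB1B, at 0.31 ± 0.08 (adjusted p = 0.0252), and WWTR1, a paralog of YAP1, was called adjusted over the list alone (0.22 ± 0.07, adjusted p = 0.0572 over all genes). Of 28 extracellular matrix and TGF-beta response genes (adjusted p = 0.134), SKIL rose by 0.33 ± 0.09 (adjusted p = 0.0316). The integrin gene ITGAV was the 1 call of 29 in the actin and focal adhesion list (0.31 ± 0.07, adjusted p = 0.0140; list adjusted p = 0.0680). Of 24 p53 targets (adjusted p = 0.513), BTG2 rose by 0.36 ± 0.08 (adjusted p = 0.0155) and MDM2 by 0.28 ± 0.07 (adjusted p = 0.0357), while GDF15 fell. The BTG2 call ended with quantile normalisation and median centring. In vector, BTG2 was at 8.11, against 8.10 in si-YAP1 and 7.74 in siNC, and MDM2 at 11.07, against 11.10 and 10.82. MOB1B in vector was at 11.15, against 11.16 in si-YAP1 and 10.84 in siNC. Vector levels of ADAM10 (12.19), SKIL (10.62), ITGAV (13.68) and WWTR1 (11.87) also lay between those of siNC and si-YAP1. Medians of the APP processing, matrix and actin lists lay above 0 although camera placed them below other genes. With the GC and length correction, chosen after seeing the data, the matrix list (adjusted p = 0.0448, median -0.04) and the actin list (adjusted p = 0.0280, median -0.03) were called lower (adjusted p = 0.285 for each with an estimated correlation). Calls of ADAM10, MOB1B, SKIL, MDM2, RBMS3 and SLC7A11 ended with quantile normalisation, median centring and the GC and length correction, and that of ITGAV with the correction (0.14, adjusted p = 0.0939).

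The overexpression comparison asks which genes respond to more YAP1, and most genes called were lower. SAMD9 (chromosome 7, 93099513 to 93118023) fell from 11.29 ± 0.35 in vector (SD, n = 3) to 10.53 ± 0.11 in YAP1 (SD, n = 2), by 0.76 ± 0.14 (SE; limma adjusted p = 0.0106), and its neighbouring paralog SAMD9L fell by 0.76 ± 0.12. RANBP2 fell by 0.72 ± 0.12, SMC2, a condensin subunit, by 0.69 ± 0.11 and TOP2A by 0.68 ± 0.10. IL6ST, the shared receptor subunit of interleukin 6 cytokines, fell by 0.66 ± 0.11 and the tyrosine kinase gene FER by 0.66 ± 0.10. JMJD1C fell by 0.63 ± 0.10, the tumour suppressor gene APC by 0.62 ± 0.13 and BCLAF1 by 0.61 ± 0.10. Adjusted p-values of these genes lay between 0.00698 and 0.0182. Of the genes tested, 281 fell and 4 rose, and 1505 had an unadjusted p under 0.05. Beside YAP1, the rises included ACLY, which makes cytosolic acetyl-CoA (chromosome 17, 41866908 to 41930542, 0.56 ± 0.14, adjusted p = 0.0481). COL6A3, a collagen VI chain, rose as well (chromosome 2, 237324003 to 237414375, 0.29 ± 0.06, adjusted p = 0.0221). The remaining rise, the largest called (0.775), was in a gene that the naming rule left out. ENSG00000184779, which has no match in the annotation and is named here after its values were seen, was not among these rises. It was high in YAP1 replicate 1 alone, at 10.53 against 8.49 to 8.79 in the other libraries. The genes that fell had a median transcript GC content of 37.8% and a median length of 6601 bases. Of the 17 named genes called, 1 kept its call with the GC slope covariate, 11 without the trend and 14 with the replicate block. The GC slope moves with group. Without YAP1 replicate 3 or YAP1 replicate 1 the calls numbered 2 and 6, and 85 and 101 without vector replicate 2 and 3, against 558 without vector replicate 1 and 504 without si-YAP1 replicate 2. None of the 17 named genes called kept its call without YAP1 replicate 3, and 2 did without YAP1 replicate 1, where the lone library of the group is assumed to vary like the others.

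After overexpression the cell cycle lists were lower and lists of matrix and lipid synthesis genes higher than other genes. All 30 members of the mitosis and G2/M list lay below 0, with a median of -0.15, and 3 fell, or 7 adjusted over the list alone (camera adjusted p = 5.28e-10; adjusted p = 0.724 with an estimated correlation). Beside TOP2A they were HMMR, a spindle-associated hyaluronan receptor (-0.60 ± 0.10 SE, limma adjusted p = 0.00898), and KIF11 (-0.47 ± 0.09, adjusted p = 0.0127). The mitosis list's median deviation was 0.14 in vector replicate 3, and -0.04 and 0.05 in vector replicates 1 and 2; without it and si-YAP1 replicate 2 the median change was -0.10 (camera adjusted p = 1.10e-10). In the DNA replication and S phase list 28 of 29 members lay below 0, with a median of -0.09 and camera adjusted p = 0.00126 (adjusted p = 0.812 with an estimated correlation), and 0 passed the limma test, 4 being lower at an unadjusted p under 0.05. That list call was lost without YAP1 replicate 3 (adjusted p = 0.259). The extracellular matrix and TGF-beta response list was higher (camera adjusted p = 0.000176, median 0.05; adjusted p = 0.724 with an estimated correlation), with 1 rise among 28 members, COL6A3. Adjusted over the list alone COL1A1 rose as well (0.28 ± 0.09) and SKIL fell (-0.31 ± 0.10). ACLY was the 1 rise among 28 cholesterol and fatty acid synthesis genes, over all genes or adjusted over the list alone (camera adjusted p = 0.00543, median 0.05; adjusted p = 0.724 with an estimated correlation). The ACLY call was lost in 13 of 22 alternatives, among them quantile normalisation (adjusted p = 0.0587) and the GC and length correction (adjusted p = 0.0721). FASN, the fatty acid synthase gene of that list, was at 0.25 ± 0.10 (adjusted p = 0.365). The list call was lost without vector replicate 3 (adjusted p = 0.0683) or YAP1 replicate 1 (adjusted p = 0.221), where its median was -0.01, and when both vector replicate 3 and si-YAP1 replicate 2 were left out (adjusted p = 0.0584). Of 29 actin and focal adhesion genes 0 passed the limma test, and at an unadjusted p under 0.05, 1 was higher and 2 lower. The list was called higher (camera adjusted p = 0.0368, median 0.05, and adjusted p = 0.807 with an estimated correlation). It lost its call with median centring (adjusted p = 0.0772), quantile normalisation (adjusted p = 0.265) and the GC and length correction (adjusted p = 0.142). The call was also lost without vector replicate 1 (0.0669) or 3 (0.0683) or YAP1 replicate 1 (0.195).

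YAP1 targets and APP-related genes were not called as groups after overexpression. The 22 genes of the YAP/TAZ signature had a median change of 0.0045 (camera adjusted p = 0.361), with 0 past the limma test and 2, both lower, at an unadjusted p under 0.05. CTGF stood at -0.20 ± 0.08 (SE; adjusted p = 0.385), CYR61 at 0.08 ± 0.07 (adjusted p = 0.805) and ANKRD1 at -0.04 ± 0.08 (adjusted p = 0.928). The APP processing list was not called (camera up, adjusted p = 0.249), with a median of -0.0018 and a mean of 0.0030, and 0 members passed the limma test, 6 being at an unadjusted p under 0.05. CD2AP, an endocytic adaptor, was at -0.38 ± 0.10 (adjusted p = 0.0559 over all genes) and fell adjusted over the list alone. LRP1, a lipoprotein receptor, was at 0.34 ± 0.11 (adjusted p = 0.203) and APP at 0.06 ± 0.08 (adjusted p = 0.865). With the GC and length correction, chosen after seeing the data, this list was called higher (adjusted p = 0.0448; adjusted p = 0.228 with an estimated correlation). In the Hippo list MOB1B fell by 0.34 ± 0.08 (adjusted p = 0.0499; list adjusted p = 0.379), a call lost in 13 of 22 alternatives, among them the GC and length correction (-0.16, adjusted p = 0.242). In the ATF4 and unfolded protein response list, SLC7A11 fell by 0.55 ± 0.11 (adjusted p = 0.0131), while the list was not called (adjusted p = 0.986). Interferon response genes (adjusted p = 0.409) and p53 targets (adjusted p = 0.361) held 0 calls, with 3 and 2 members lower at an unadjusted p under 0.05.

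The 2 control groups received different nucleic acids, siRNA or plasmid, and also differed from each other. Vector cells expressed more of NPY1R than siNC cells, 14.38 ± 0.04 against 13.54 ± 0.32 (SD, n = 3 each; 0.83 ± 0.13 SE, limma adjusted p = 0.00821), and less of CHAC1, 10.06 ± 0.03 against 10.59 ± 0.09 (-0.53 ± 0.06, adjusted p = 0.00223). Rises followed in SCUBE3 (0.61 ± 0.11), AJAP1 (0.57 ± 0.11) and SMC2 (0.51 ± 0.09). PCDH1 fell by 0.51 ± 0.09, TRIB3 by 0.48 ± 0.07, GDF15 by 0.47 ± 0.07 and the immediate early gene EGR1 by 0.47 ± 0.07. In all, 231 genes were higher and 36 lower in vector, and 2531 had an unadjusted p under 0.05. The ATF4 and unfolded protein response list was lower (camera adjusted p = 2.14e-14, median -0.15), with 6 falls of 30 members, or 14 falls and 2 rises adjusted over the list alone, among them the amino acid transporter gene SLC7A5 (-0.42 ± 0.07). The DNA replication list (adjusted p = 6.31e-07, median 0.15), the mitosis list (adjusted p = 4.19e-05, median 0.15), cholesterol and fatty acid synthesis (adjusted p = 0.00175, median 0.11) and glial markers (adjusted p = 0.00262, median 0.12) were higher. Past the limma test were 0, 3, 3 and 2 of their members, or 12, 10, 10 and 3 adjusted over the list alone, and 17 DNA replication genes were higher at an unadjusted p under 0.05. TOP2A rose by 0.46 ± 0.09 (adjusted p = 0.0143), HMGCS1, of cholesterol synthesis, by 0.25 ± 0.06 (adjusted p = 0.0499) and GFAP by 0.40 ± 0.10 (adjusted p = 0.0458), the calls of HMGCS1 and GFAP ending with quantile normalisation and median centring. Interferon response genes (adjusted p = 1.19e-08, median -0.11), NF-kB and cytokine genes (adjusted p = 3.16e-05, median -0.05) and ribosomal proteins (adjusted p = 0.000182, median -0.05) were lower, with 0 members past the limma test and 5, 4 and 2 lower at an unadjusted p under 0.05. Each of these 8 lists had an adjusted p of at least 0.724 with an estimated correlation. Calls split 149 and 101 with median centring, 182 and 72 with quantile normalisation and 136 and 93 with the GC and length correction. They numbered 3, 46 and 46 without siNC replicate 1, 2 or 3, 8 and 88 without vector replicate 2 or 3, 152 and 151 without YAP1 replicate 1 or 3, 719 without vector replicate 1, 786 without si-YAP1 replicate 2, and 469 without si-YAP1 replicate 2 and vector replicate 3 together. Of the 19 named genes called, 17 lost their call without siNC replicate 1 and 15 without vector replicate 2, and the cholesterol list lost its call without vector replicate 1 (adjusted p = 0.130).

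**Figure D3:**
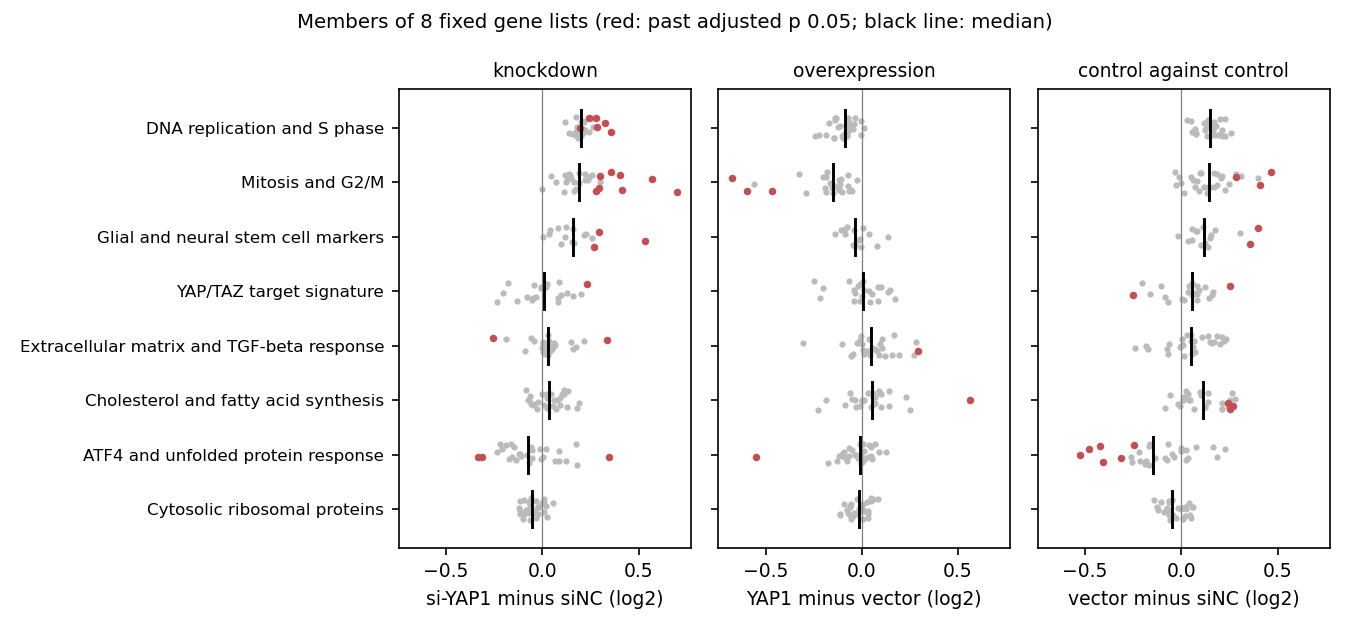
Each point is a member of a fixed gene list, placed by its log2 change in the comparison named on the x axis, red where it passed adjusted p 0.05 in limma and grey otherwise, with the list median as a black line; vertical scatter is random. Medians of the mitosis list lie at 0.19 after knockdown, -0.15 after overexpression and 0.15 between the controls, and those of the ATF4 list at -0.07, -0.01 and -0.15.

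Knockdown was then compared with overexpression. Of 15681 genes, 233 were called in both comparisons, and all 233 rose after knockdown and fell after overexpression, against 12.8 expected from independent lists (one-sided Fisher's exact test across genes, which are not independent, p = 6.75e-277). The comparisons share no libraries, but each gene's spread was estimated once over all 11 libraries. The 2 lists are thus not independent, and 12.8 may be too low an expectation. By the smaller of the 2 changes the leading genes were SAMD9, RANBP2, SMC2, APC and CHD9. Each already lay higher in vector (11.29, 11.30, 10.08, 10.07 and 12.32) than in siNC (10.96, 10.82, 9.57, 9.67 and 11.87). YAP1 was at 12.13 in vector and 12.07 in siNC. In the YAP1 libraries these genes averaged 10.53, 10.58, 9.39, 9.45 and 11.72, each below siNC. SMC2 rose by 0.61 ± 0.09 (SE) and fell by 0.69 ± 0.11, APC rose by 0.61 ± 0.12 and fell by 0.62 ± 0.13, and CHD9 rose by 0.62 ± 0.10 and fell by 0.60 ± 0.11. Across all tested genes the changes correlated at Pearson's r = -0.599 and Spearman's rho = -0.474, and genes are not independent replicates. A direct test of the difference between the 2 effects called 1271 genes, 1241 with a lower value for overexpression and 30 with a higher one, among them YAP1 (0.55 ± 0.09, limma adjusted p = 0.000584) and KRT81 (0.96 ± 0.11, adjusted p = 9.94e-05). KRT81 was at 0.32 ± 0.08 after overexpression (adjusted p = 0.0560). Its levels in vector (10.22) and YAP1 (10.53) both lay below that in siNC (10.62). With the GC and length correction 123 genes were called in both in opposite directions, 119 and 4 by direction against 3.63 and 0.140 expected, and 110 of the original 233 were among them; the difference then had 295 genes higher and 560 lower, and 387 and 737 with median centring. The 233 became 0 and 4 without YAP1 replicate 3 or 1, 52, 64 and 151 without siNC replicate 1, 2 or 3, 134 without si-YAP1 replicate 2, 79 and 89 without vector replicate 2 or 3, 418 without vector replicate 1, and 240 without si-YAP1 replicate 2 and vector replicate 3 together, and the difference had 467 and 787 calls without YAP1 replicate 3 or siNC replicate 1.

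**Figure D4:**
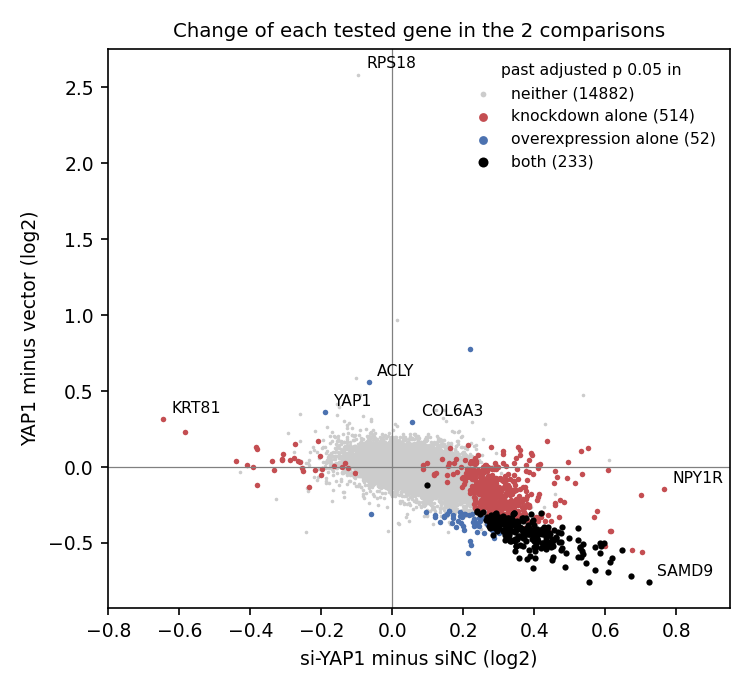
Each point is a tested gene, placed by its log2 change after knockdown (x axis) and overexpression (y axis) and coloured by the comparisons in which it passed adjusted p 0.05 in limma. The 233 genes called in both lie at the lower right, higher after knockdown and lower after overexpression, and RPS18, at the top and named after its values were seen, is high in YAP1 replicate 3 alone.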

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

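The GC and length correction, the GC slope covariate and the omission of si-YAP1 replicate 2 with vector replicate 3 were chosen after seeing the data. Counts of calls moved by over 1.5 times in these settings, and the cause was not tested except where a stricter threshold or fewer libraries set it. Without the trend, 99 genes were called after overexpression, 78 between the controls and 79 in both comparisons. Quantile normalisation gave 321 after knockdown and 142 in both, and median centring 435 and 154. Fitting the control groups alone gave 625. A minimum change of 0.5 left 39 after knockdown, 55 after overexpression, 11 between the controls, 591 for the difference and 21 in both. The GC and length correction gave 418 after knockdown and 123 in both, with r = -0.487. The GC slope covariate, which moves with group, left 466 after knockdown, 7 after overexpression, 148 between the controls, 254 for the difference and 5 in both. Omitting both libraries gave 469 between the controls and r = -0.396. YAP1 passed the test in the knockdown with quantile normalisation (-0.28), median centring (-0.28), the GC and length correction (-0.30), the GC slope (-0.21) and both libraries out (-0.19), with adjusted p between 0.00313 and 0.214 over its alternatives. With an estimated correlation 0, 0 and 0 lists were called in the knockdown, overexpression and control comparisons (1, 0 and 2 at an unadjusted p under 0.05), and with fry 0, 0 and 0 (5, 1 and 6). Leaving out 1 library gave 82 (siNC replicate 1) to 1116 (vector replicate 3) calls after knockdown and 2 (YAP1 replicate 3) to 558 (vector replicate 1) after overexpression. It gave 3 (siNC replicate 1) to 786 (si-YAP1 replicate 2) between the controls, 467 (YAP1 replicate 3) to 1773 (vector replicate 1) for the difference, 0 (YAP1 replicate 3) to 418 (vector replicate 1) in both, and r of -0.649 (si-YAP1 replicate 3) to -0.395 (si-YAP1 replicate 2). YAP1 ranged from -0.23 to -0.16 in the knockdown and 0.33 to 0.39 in the overexpression. Lists called ranged from 7 to 10, 3 to 6, and 8 to 8. With the replicate block 163 genes were called after overexpression and 147 in both. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.35 to 0.42, and 3 of 11 libraries correlated best with their own number. Of 76 called results for named genes, 15 kept their call in every alternative, 12 lost it with the GC and length correction and 5 with the block, and 0 changed direction in a called alternative. Unknown depth limits what low values can show.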

Other observations

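The GC content test of the cell cycle lists and the test of YAP1 dependence of the ATF4 list were chosen after the result was seen, as were the GC and length correction and the omission of 2 libraries that other tests below use.

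Markers of other cell types were not called. The 9 tested neuron markers had medians of 0.10 after knockdown and -0.06 after overexpression (camera adjusted p = 0.968 and 0.379), and 0 passed the limma test, 3 and 0 having an unadjusted p under 0.05. Camera placed the list below other genes after knockdown although its median lay above 0. MAP2, a neuronal microtubule protein, was at 0.29 ± 0.09 (SE) after knockdown (adjusted p = 0.0786). The 7 epithelial and endothelial markers had camera adjusted p of 0.0680 and 0.215, with 0 members past the limma test and 0 and 0 at an unadjusted p under 0.05. CSF1R, the 1 tested microglia and leukocyte marker, stood at 5.99 ± 0.09 in si-YAP1 and 6.04 ± 0.07 in siNC (SD, n = 3 each). The 30 oxidative phosphorylation genes had medians of 0.03 and -0.01 (adjusted p = 0.0680 and 0.513), and the 7 replication-dependent histone genes 0.04 and -0.01 (adjusted p = 0.811 and 0.490), each with 0 members past the limma test, and 1 and 0 of each list at an unadjusted p under 0.05. Cholesterol and fatty acid synthesis genes were not called after knockdown (adjusted p = 0.267), nor were NF-kB and cytokine genes (0.513), hypoxia and glycolysis genes (0.924), ribosomal proteins (0.652) or glial markers (0.968) after overexpression.

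Interferon response genes differed between libraries of 1 group. Per library, the list's median deviation averaged 0.19 ± 0.22 in si-YAP1, 0.04 ± 0.14 in siNC and -0.10 ± 0.22 in vector (SD, n = 3 each), and -0.21 ± 0.08 in YAP1 (SD, n = 2). After knockdown the list was not called (camera adjusted p = 0.554), with IFI44L at 0.39 ± 0.14 (SE, adjusted p = 0.119) and DDX58, a sensor of viral RNA, at 0.32 ± 0.12 (adjusted p = 0.144). RPS18, a ribosomal protein gene, was at 11.68 in YAP1 replicate 3 and between 6.39 and 6.80 in the other libraries.

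In the first pattern, genes moved in opposite directions after knockdown and overexpression. The leading genes SAMD9, RANBP2, SMC2, APC and CHD9 were also higher in vector than in siNC, at YAP1 levels of 12.13 and 12.07. After the GC and length correction 123 genes were still called in opposite directions, far above the number independent lists give (3.63 and 0.140 by direction). This argues against GC content and length as the whole cause only as far as the correction removes them. An incomplete correction could also leave such genes, and r was then -0.487. With the GC slope covariate 16 of the 17 named overexpression calls were lost. That covariate moves with group, so it cannot separate composition from a YAP1 effect. A library difference that also separates libraries within a group remains open. The contrast of vector replicate 3 with its group correlated at r = 0.394 with the knockdown effect of all 6 libraries, none of them vector. That of si-YAP1 replicate 2 correlated at r = -0.496 with the overexpression effect of all 5 libraries. Without si-YAP1 replicate 2 in the knockdown the former r was 0.145. Without vector replicate 3 in the overexpression the latter r was -0.326. With both libraries out, 240 genes were called in both comparisons, 238 in opposite directions and 2 in the same one, which argues against these 2 libraries alone as the cause, while r fell in size to -0.396. All of these within-group r have the sign the explanation needs, but 0.145 is neither near 0 nor large. A difference shared with the other libraries therefore cannot be told apart from an effect of YAP1 level, which the design names and which stays open.

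In the second pattern, cell cycle lists were higher after knockdown and lower after overexpression. After the GC and length correction the 4 list tests kept their directions, with a largest camera adjusted p of 1.27e-07 at the preset correlation. With an estimated correlation the largest was 0.299. At the preset, camera also called up to 9 lists in other splits of the knockdown libraries. The test therefore cannot decide against composition as the whole cause. Without si-YAP1 replicate 2 and vector replicate 3 the directions stayed, with a largest adjusted p of 3.59e-05 at the preset correlation. The directions thus did not come from those libraries alone, while the p-value has the same limit. With an estimated correlation the 4 tests were not past the threshold, and the lists were also higher in vector than in siNC, so a YAP1 effect on the cell cycle may be considered only as a hypothesis beside a difference in growth between cultures, which was not tested.

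In the third pattern, the ATF4 and unfolded protein response list was lower after knockdown. The list was higher in si-YAP1 than in vector (unadjusted camera p = 0.00294 across genes, mean difference 0.07; a permutation of the 6 libraries cannot go below 0.1), and vector lay further below siNC (-0.13) than si-YAP1 did (-0.06), which is consistent with a high level in the siNC libraries. With an estimated correlation of 0.315 this unadjusted camera p was 0.324, past no threshold, so a high siNC level stays a candidate explanation only, which a permutation of so few libraries could not decide. Dependence on YAP1 could not be decided, since after overexpression the list had an adjusted p of 0.986 and a mean change of -0.04. Whether a high siNC level came from the control siRNA or from the cultures was not tested.

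The 6 libraries of the knockdown comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 747 genes, and 1 of 10 splits reached that, the highest other giving 0 (limma, with 1015 at an unadjusted p under 0.05 against 3242). The real split gave 8 lists, and 3 of 10 splits reached that, the highest other giving 9. For vector against siNC the same holds, with 267 genes in the real split, reached by 1 of 10, and 0 in the highest other (1089 against 2531 at an unadjusted p under 0.05), and with 8 lists in the real split, reached by 3 of 10, the highest other giving 8.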
